A study of Homo sapiens with 14 samples.

How the data were processed

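RNA came from THP-1 cells, an established human acute monocytic leukaemia line used as a model of monocytes. The cells were unstimulated or stimulated with arachidonic acid (AA, a polyunsaturated fatty acid and the precursor of prostaglandins and leukotrienes) or oleic acid (OA, a monounsaturated fatty acid), each at 1, 10 or 100 µM. The 7 conditions had 1 Affymetrix human exon array each. Every array was deposited in 2 forms, a gene-level table of transcript clusters and an exon-level table of probe sets, so the 14 deposited columns stand for 7 hybridisations. Neither the length of stimulation nor the vehicle of the acids is given in the sources used here. According to the series record, the cells also served for DNA methylation arrays, which were not analysed here.

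Per the submitters' processing notes, the authors processed the arrays with Affymetrix Expression Console and RMA on build hg18. The deposited values of both tables were taken as log2 signals, as RMA gives them, although the log base is not written in the tables. RMA in its usual form corrects background, makes the distributions of the arrays equal before probes are summarised, and summarises by median polish. Median polish can give several arrays exactly the same value for a gene, and 67.6% of the tested transcript clusters held such a tie. A tie makes the spread between arrays look smaller than it is. No scanner files were used here, so no background signal per array was known, and the number of arrays sets the precision.

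The gene-level table held 133672 transcript clusters. A table of platform annotation gave 1 gene symbol for 19963 of them, several for 3352 and none for 110357. Symbols were checked against a RefSeq gene table through gene identifiers, 56 symbols had no entry there, and no symbol changed. Clusters with 1 symbol and a mean over the 7 arrays at or above their median of 6.00 (log2) were tested, which left 9982 clusters of 9268 genes. The exon-level table held 1048575 probe sets, of which 356838 had 1 symbol, 15267 several and 676470 none, and 178419 of the named ones were at or above their median mean of 6.70. Its highest probe set identifier was 4056214, and 71 clusters of the gene-level table had a higher one, so the exon-level table may hold only part of the array. Older symbols of probe sets were replaced where they were a synonym of 1 gene. No genome coordinates were used, because the annotation at hand was of another build.

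Tests were run in R 4.3.3 with limma 3.58.1, with the package data.table, version 1.17.8, for reading, and plots were drawn in Python 3.11.15 with matplotlib 3.10.9. Because each condition had 1 array, no condition had a spread of its own, and each test took its spread from other arrays. The models, the alternatives, the rule for named genes and the gene lists were fixed before the data were examined, except where stated. The main model was a straight line over dose steps from unstimulated to 100 µM with 1 slope per acid, fitted with lmFit and eBayes with an intensity trend. It had 4 residual degrees of freedom and used all 7 arrays. The difference of the slopes compared the acids, and a second model compared AA with OA on the 6 treated arrays with dose as a block, with 2 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values and the threshold was 0.05. These p-values measure departures of single arrays from the model, which may be technical, since nothing says that cultures were repeated.

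After the data had been seen, a comparison was added in which each 100 µM array was set against the 4 arrays at 1 and 10 µM, without the unstimulated array. It had 3 residual degrees of freedom, all from those 4 arrays, and the lone 100 µM arrays were assumed to vary like them. "Rose", "fell" and "changed" below refer to an adjusted p under 0.05 in that comparison. It is called the top-dose comparison. Intervals are 95% intervals from the moderated fit.

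The genes named were chosen by a rule. For each slope and for the difference, the 12 largest positive and the 12 largest negative of the genes past the threshold were named. Where fewer passed, the set was filled to 12 with the genes of largest difference between 100 µM and unstimulated cells, or between the acids at 100 µM, whose 100 µM value lay outside the range of the 5 other arrays considered. The same rule was then applied to the top-dose comparison. Of each gene list, members past the threshold and up to 4 with the largest slopes could be named. Of several clusters of 1 gene the brightest was used. Other genes, such as DNMT1, DNMT3A, TET2, GPAM, MID1IP1, ACACA, PMVK and the genes below the signal filter, were singled out after their values were seen. The counts of the unstimulated array over other sets of clusters and the sterol list values without ties or with rebuilt genes, and the directions over all probe sets of a gene, were also chosen after the data had been seen.

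There were 23 gene lists, and the 21 with at least 3 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. With an estimated correlation, camera works on the residual degrees of freedom of the fit, 4 in the line model and 3 in the top-dose comparison. So few leave it little power over 63 tests, so a list that failed it was not shown to be unshifted. The lists covered PPAR-responsive lipid genes, cholesterol synthesis and uptake, fatty acid synthesis, LXR targets, the eicosanoid pathway, ATF4 and the unfolded protein response, NRF2 and oxidative stress, heat shock, metallothioneins, NF-kB and inflammatory cytokines, interferon response, monocyte to macrophage markers, DNA methylation machinery, histone deacetylases and sirtuins, cell cycle, p53 targets, TGF-beta and BMP signalling, glycolysis and hypoxia, the respiratory chain, ribosomal proteins, and lymphoid, epithelial and fibroblast, and erythroid markers. A list's median was also placed among 10000 random lists of the same size and similar brightness. Of the 63 tests in each model, 14 passed in the line model and 8 in the top-dose comparison, and 0 of either held with an estimated correlation. The median, the mean and the tested direction of a list differed in sign for 8 of 21 lists with AA and 6 with OA at the top dose, 0 of them called.

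The models were tested on simulated arrays with 200 of 9982 clusters changed. The simulated unstimulated array was given the real one's spread of differences across clusters, but not its median offset. With it, the line model recovered 60% of clusters changed by 0.5 log2 per step and 90% of those changed by 1. These shares need not hold for the real arrays, which carry the offset. The top-dose comparison recovered 67% of clusters changed by 0.5 log2 on the 100 µM AA array and 90% of those changed by 1, with 5 and 11 false calls. The list test found the 1 shifted list and called 0 of the 20 others. Simulated values had no ties and were drawn independently for each cluster. The list test was therefore not tried on lists whose members vary together, and its lack of false calls does not cover them. It was tried only at the preset correlation. Alternatives covered the signal filter, centring and quantile normalization of the tested clusters, the dose scale, the variance prior, array weights, gene values rebuilt as medians of probe sets, clusters without ties, and leaving out single arrays.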

Results

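The data were gene expression profiles of THP-1 monocytes, 1 array for unstimulated cells and 1 for each of 3 doses of AA and of OA. The 6 treated arrays resembled each other closely, with correlations between 0.977 and 0.994 across the tested clusters in their 15 pairs. The unstimulated array stood apart, with correlations between 0.702 and 0.746 to the treated ones. Its median signal over tested clusters was 6.46 (log2) against 7.23 to 7.30 on the treated arrays. Of the tested clusters, 84.7% were higher on all 6 treated arrays than on the unstimulated one and 6.07% were lower on all 6, where chance gives 14.3% each. Every difference from the unstimulated array below carries this offset, a median of 0.82 log2. The offset depended on the clusters counted. Over all 133672 clusters the unstimulated median was higher, 4.84 against 4.60 to 4.62, its correlations with the treated arrays were 0.813 to 0.837, and 29.3% of clusters were higher on all 6 treated arrays and 36.0% lower. Among clusters chosen by their signal on the unstimulated array alone, 71.1% were higher on all 6 and 16.6% lower.

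**Figure D1:**
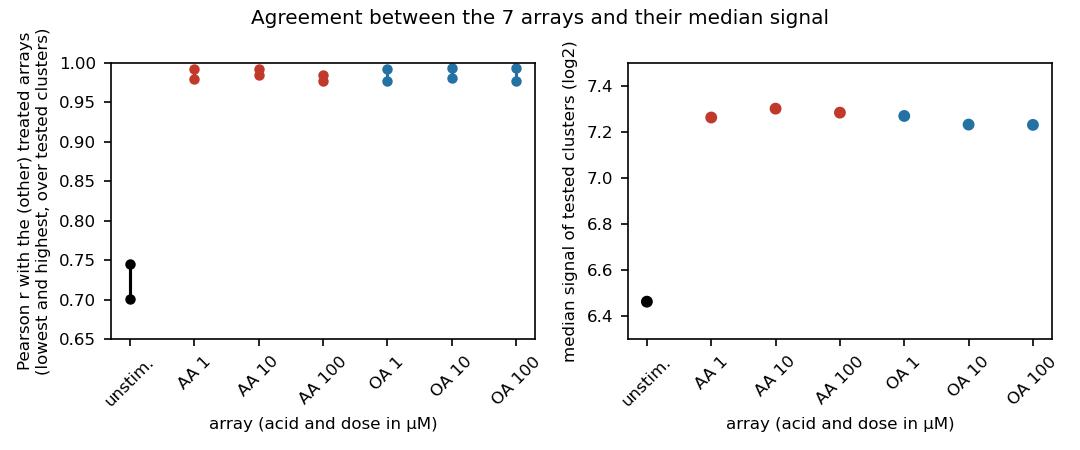
Left, lowest and highest Pearson correlation of each array with the treated arrays over tested clusters (black unstimulated, red AA, blue OA, doses in µM). Right, median log2 signal of the tested clusters on each array; the unstimulated array lies at 6.46 and the treated arrays between 7.23 and 7.30.

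The question of the series was how expression changes with increasing AA or OA. The planned dose lines over all 7 arrays called no gene, and the changes given for 100 µM come from the top-dose comparison, which was chosen after the data had been seen. GPR183, an oxysterol-sensing chemotactic receptor, was 9.63 on the 100 µM AA array against 7.39 ± 0.34 (SD, 4 arrays at 1 and 10 µM), a rise of 2.24 log2 (adjusted p = 0.040, limma). LTBP1, which binds latent TGF-beta, rose by 1.74 (adjusted p = 0.018), FCAR, the IgA receptor, by 1.35, C1QA, a complement subunit, by 1.16 and PLAUR, the urokinase receptor, by 1.01. SIRPB1, a signal-regulatory receptor, fell by 0.99 (adjusted p = 0.010), and the chemokine genes CCL2 and CCL5 and the chemokine receptor CX3CR1 fell by 0.89, 0.72 and 0.85.

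Among the other genes the rule named at 100 µM AA, the non-coding RNA LINC01226 rose by 2.27, LRRC37B by 1.74, DHCR7, the last enzyme of cholesterol synthesis, by 1.22, CABLES1 by 1.11, SYTL3 by 0.99, CPEB2 by 0.96 and FNDC3A by 0.96. PTX3, a soluble pattern recognition protein, fell by 0.86, MAPK8IP2 by 0.79, the transcription factor gene NFIX by 0.73, PTGS1, which encodes cyclooxygenase-1, by 0.65, PHACTR3 by 0.63, SIRPD by 0.63 and LCA10 by 0.56. LINC01226 and LCA10 had no probe sets assigned to their symbols alone, so neither could be checked by probe sets or rebuilt values. The cluster of the pseudogene HNRNPA1P27 fell by 1.06, but its values were those of 1 probe set below the signal filter. Of its 14 probe sets, by sign alone, 11 were higher and 3 lower than at the lower doses, with a median difference of 0.15. Of the 5 above the filter 0 were lower, so a fall of this gene is not supported. With gene values rebuilt from probe sets, LRRC37B (0.56), SIRPB1 (-0.36) and MAPK8IP2 (-0.38) kept their direction and were no longer called. The rebuilt difference of HNRNPA1P27, between medians of its 14 probe sets on each array, was -0.33 and not called, although most of them were higher by sign. C1QA (0.61), PTGS1 (-0.31) and SIRPD (-0.70) were not called with rebuilt values either. Over the 64 called genes named for 100 µM AA that had rebuilt values, gene list members included, 24 were still called, 37 had the same direction without a call and 3 had the opposite direction.

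Some larger differences did not pass, among them genes whose 10 µM AA value also lay above the other lower-dose values. PRDM1, which encodes the transcription factor BLIMP-1, was 6.10, 7.09 and 8.91 at 1, 10 and 100 µM AA and between 5.95 and 6.04 at the same doses of OA (top-dose difference 2.60 with a 95% interval from 1.16 to 4.03, adjusted p = 0.069). The immediate-early gene FOS was 7.65, 8.45 and 9.05 with AA (adjusted p = 0.25). The formyl peptide receptor gene FPR2 was 5.88, 6.45 and 7.53 with AA, and CXCL8, the gene of interleukin-8, was 7.75, 8.19 and 8.88.

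In the top-dose comparison, 584 clusters rose and 253 fell at 100 µM AA (limma, 9982 tested; 2460 at an unadjusted p under 0.05). This count hung on single arrays: it was 0 without the 1 µM AA array, 0 without the 10 µM OA array (2050 and 2221 at an unadjusted p under 0.05) and 1650 without the 10 µM AA array. Every gene called at 100 µM AA, list members included, thus lost its call without either of the first pair. The count was also larger where ties understated the spread, with calls in 4.20% of clusters with no tie among the 4 lower arrays and in 30.6% of those with 4 equal values. In the planned line model with all 7 arrays, 0 clusters passed for the AA slope (775 at an unadjusted p under 0.05, smallest adjusted p 0.29).

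Genes of NRF2 and oxidative stress defence were the list with the clearest shift at 100 µM AA: 7 of 14 measured members rose and 0 fell, the same 7 and 0 when adjusted over the list alone. These were SLC7A11, the cystine importer (9.94 against 9.09 ± 0.11, 0.85 log2), PGD of the pentose phosphate pathway (0.84), TXNRD1, thioredoxin reductase (0.61), GCLM, a subunit of the first enzyme of glutathione synthesis (0.60), CAT, catalase (0.53), HMOX1, heme oxygenase 1 (0.46), and TKT, transketolase (0.42). The list test gave an upward shift (adjusted p = 4.7e-06, camera), and an adjusted p = 0.98 with an estimated correlation. GCLM and HMOX1 each had the same value on the 4 arrays at 1 and 10 µM, so their spread was understated. With rebuilt gene values HMOX1 was no longer called and the other 6 were.

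PPAR-responsive lipid genes included 6 of 16 measured members that rose and 0 that fell, again 6 and 0 when adjusted over the list alone. CPT1A, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, rose by 0.60 and ACADVL, the very long-chain acyl-CoA dehydrogenase, by 0.59. ETFDH rose by 0.56, SLC25A20, the carnitine carrier, by 0.53, ACSL1 by 0.35 and HADHB by 0.25. The list shifted upward (adjusted p = 0.0076, and adjusted p = 0.98 with an estimated correlation), but over the 5 members without ties the adjusted p was 0.70. With rebuilt gene values ACADVL was called and the other 5 members were not. Among fatty acid synthesis genes, 3 of 11 fell and 0 rose, against 4 and 1 when adjusted over the list alone: FASN, fatty acid synthase, fell by 0.35, SCD, stearoyl-CoA desaturase, by 0.34 and SREBF1, a transcription factor of lipid synthesis, by 0.26. That list shifted downward (adjusted p = 0.035; adjusted p = 0.98 with an estimated correlation). FASN, SCD and SREBF1 were not called with rebuilt gene values. The list's adjusted p was 0.11 with rebuilt gene values, 0.15 without the signal filter, 0.053 without the 1 µM AA array, 0.27 without the 10 µM AA array and 0.083 without the 1 µM OA array.

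Of 27 cell cycle genes 7 rose by small amounts (10 adjusted over the list alone), 0 fell and 20 did not pass: the kinetochore genes CENPE (0.37) and CENPF (0.23), CDK1 (0.29), CCNB2 (0.26), AURKA (0.25), MCM6 (0.18) and CCNA2 (0.16). The list test gave adjusted p = 0.0035, and adjusted p = 0.98 with an estimated correlation. CDK1 had no rebuilt value, and the other 6 were not called with rebuilt values. The inflammatory list split, with CXCL2, a neutrophil chemokine, up by 0.82 and CCL2, PTX3 and CCL5 down, so that 1 of 11 rose and 3 fell (1 and 4 adjusted over the list alone). Its list test gave adjusted p = 0.40. Of 17 eicosanoid pathway genes 2 rose and 2 fell under both adjustments: TBXAS1, thromboxane synthase (0.32), and LTA4H, leukotriene A4 hydrolase (0.16), rose, and PTGS1 and PTGES3 (-0.26) fell. PTGES3 had the opposite sign with rebuilt gene values, and TBXAS1, LTA4H and PTGS1 were not called with them.

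**Figure D2:**
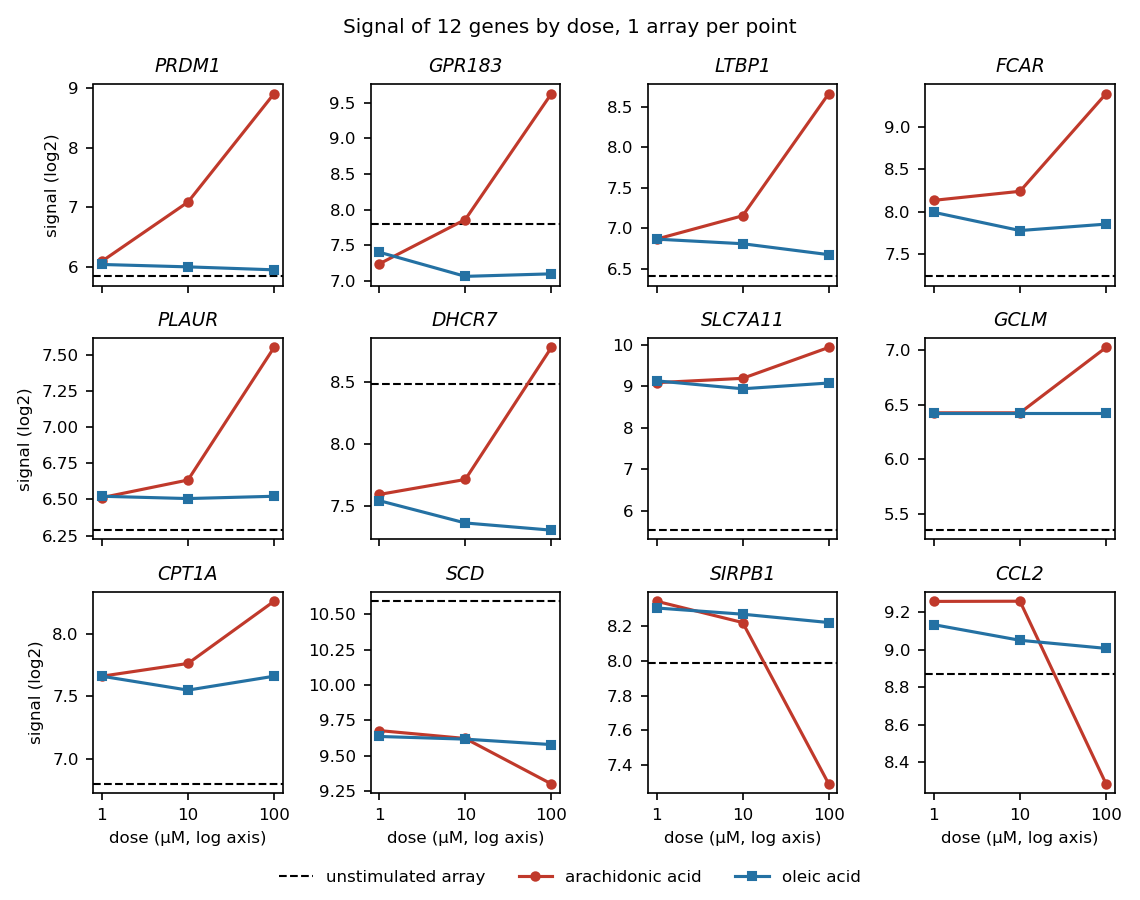
Log2 signal of 12 genes against dose in µM (log axis) for AA (red circles) and OA (blue squares), 1 array per point, with the unstimulated array as a dashed line. GPR183 reaches 9.63 and PRDM1 8.91 at 100 µM AA, while SIRPB1 and CCL2 fall there.

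The remaining lists gave few calls at 100 µM AA. Of 8 monocyte to macrophage markers 2 rose (3 adjusted over the list alone), CHI3L1 by 0.21 and ITGAX by 0.07, with a list adjusted p of 0.064 (0.98 with an estimated correlation). It was 0.045 without the 1 µM AA array and 0.027 without the 10 µM OA array, but 0.29 without the 10 µM AA array, 0.088 without the 1 µM OA array, 0.75 with rebuilt gene values, 0.50 without the signal filter and 0.22 without ties. Cholesterol synthesis and uptake had 1 rise, DHCR7, and 1 fall, TMEM97 (-0.14), of 16 under both adjustments, and TGF-beta and BMP signalling had 3 rises of 16 under both, BMPR2 (0.28), ID2 (0.20) and ACVR1 (0.15). Glycolysis and hypoxia had 2 rises of 16, NDRG1 (0.29) and PFKFB4 (0.08), and 1 fall, VEGFA (-0.42), under both adjustments. The respiratory chain had 1 rise, NDUFC1 (0.37), and 1 fall, NDUFV1 (-0.23), of 20 under both. PFKFB4 and NDUFC1 had the opposite sign with rebuilt gene values, and of the other genes named here DHCR7 alone was called with them.

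Single members were called in other lists. SLC7A11 was the 1 of 23 ATF4 and unfolded protein response genes that rose (1 adjusted over the list alone), SIRT5 (0.23) the 1 of 14 histone deacetylases and sirtuins (1), CDKN1A (0.21) the 1 of 12 p53 targets (1 rose and 1 fell) and IFI6 (0.12) the 1 of 8 interferon genes (2). SREBF1 was the 1 of 4 LXR targets that fell (2), PAX5 (-0.15) the 1 of 8 lymphoid markers (1 rose and 2 fell) and RPS24 (-0.15) the 1 of 25 ribosomal protein genes (0). With rebuilt gene values SLC7A11 and RPS24 were called and SIRT5, CDKN1A, IFI6, SREBF1 and PAX5 were not. The 21 measured genes of DNA methylation and demethylation, the 8 heat shock genes and the 5 epithelial and fibroblast markers had 0 calls under both adjustments. DNMT1, the maintenance methyltransferase, differed by -0.10 (95% interval -0.27 to 0.07), DNMT3A by -0.02 (-0.12 to 0.08) and TET2 by -0.03 (-0.23 to 0.17). Of metallothioneins 2 and of erythroid markers 1 were measured, too few for a list test, with 0 calls over all genes and 1 fall among metallothioneins over the list alone.

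The 100 µM OA array lay close to those at lower doses, and correlated at 0.994 with the 10 µM OA array. At 100 µM OA, 0 clusters were called in the top-dose comparison (limma, 789 at an unadjusted p under 0.05, smallest adjusted p 0.058), and 0 members of any list were called over all genes. Adjusted over the list alone, 1 rose and 1 fell among PPAR-responsive and among NRF2 genes, 1 rose and 2 fell among fatty acid synthesis genes, INSIG1 fell in the cholesterol list, PTGDS rose in the eicosanoid list and PAX5 among lymphoid markers, with 0 in the others. CPT1A lay at 7.66 against 7.66 ± 0.09 at the lower doses (difference 0.00, 95% interval -0.24 to 0.25), SLC7A11 differed by -0.01 (-0.31 to 0.29) and SCD by -0.06 (-0.15 to 0.03). INSIG1, a sterol-regulated brake on lipid synthesis, was 6.90 at 100 µM OA against 7.21 ± 0.04 (-0.31, -0.42 to -0.20, adjusted p = 0.19, 0.022 over the list alone). MMP1, a collagenase gene, differed by -0.45 from 6.46 ± 0.03 (adjusted p = 0.064), and RPL6, a ribosomal protein gene with many pseudogene copies, was 6.02 against 6.68 ± 0.11 (adjusted p = 0.25). In list tests of 100 µM OA the smallest adjusted p was 0.071, for inflammatory genes on the lower side, and adjusted p = 0.98 with an estimated correlation. At the preset correlation that list had 0.020 with rebuilt gene values, 0.044 without ties and 0.0047 without the 10 µM OA array, but 0.092 without the signal filter, 0.14 without the 1 µM AA array, 0.32 without the 10 µM AA array and 0.12 without the 1 µM OA array. The ATF4 list had 0.23 (0.98 with an estimated correlation), 0.027 without the 10 µM OA array and 0.065 to 0.53 in the other settings. The count of clusters was 361 without the 10 µM AA array and 332 without the signal filter. The line model also called 0 clusters for the OA slope (limma, 155 at an unadjusted p under 0.05, smallest adjusted p 0.33).

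**Figure D3:**
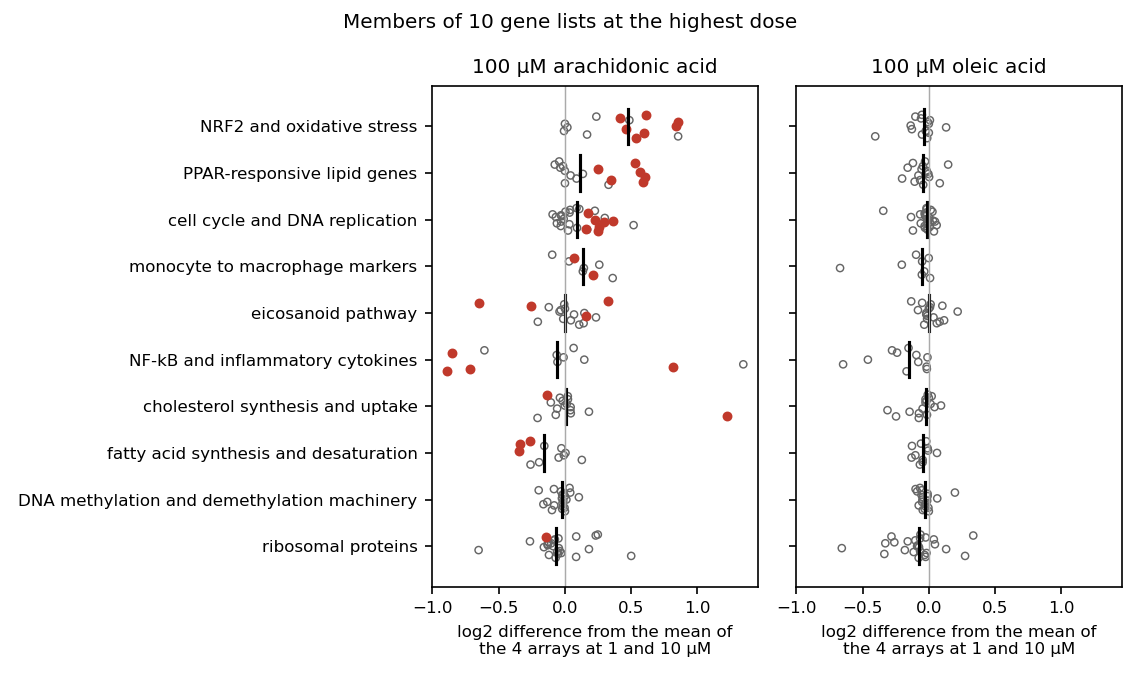
Log2 difference of each measured member of 10 gene lists from the mean of the 4 arrays at 1 and 10 µM, at 100 µM AA (left) and 100 µM OA (right); filled red points were called, open points were not, and the black bar is the list's median. The NRF2 list has 7 filled points of 14 with AA and 0 with OA.

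The single arrays of the acids, AA polyunsaturated and OA monounsaturated, lay 2-fold apart in more clusters at the highest dose than below it. AA minus OA reached 2-fold in 4 clusters higher and 1 lower with AA at 1 µM, in 4 and 1 at 10 µM, and in 30 and 4 at 100 µM. At 100 µM, LTBP1 was 1.99 log2 higher with AA than with OA (95% interval 1.44 to 2.53, adjusted p = 0.023), PLAUR 1.03 (0.81 to 1.25) and MMP1 1.22 (adjusted p = 0.005). The NRF2 list had 7 of 14 members higher with AA (7 higher and 1 lower adjusted over the list alone), with GCLM 0.60 and HMOX1 0.59 higher, and the PPAR list 5 of 16 (8 higher and 1 lower). Cell cycle genes had 4 higher (8), the cholesterol list 2, DHCR7 and INSIG1 (2 higher and 1 lower), and the fatty acid synthesis list 3 lower (1 higher and 4 lower). SIRPB1 differed by -0.93 (-1.12 to -0.74, not called with rebuilt gene values) and FASN by -0.34 (-0.47 to -0.22). Tested as the difference between the 100 µM arrays, 487 clusters were higher with AA and 242 lower (limma, 2399 at an unadjusted p under 0.05). This count was also 0 without the 1 µM AA array or without the 10 µM OA array (2091 and 2168 at an unadjusted p under 0.05), and 1781 without the 10 µM AA array.

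In list tests of that difference, NRF2 (adjusted p = 2.8e-04), PPAR-responsive (0.0082), cell cycle (0.0076) and monocyte to macrophage genes (0.035) were shifted toward AA, each with an adjusted p = 0.98 with an estimated correlation. The macrophage list had an adjusted p of 0.25 without the 10 µM AA array, 0.053 without the 1 µM OA array, 0.51 with rebuilt values, 0.63 without the signal filter and 0.078 without ties. The cell cycle list had 0.21 with rebuilt values, and the PPAR list 0.58 over the 5 members without ties and 0.063 without the signal filter. DNMT1 differed by -0.05 (-0.27 to 0.16) and DNMT3A by 0.01 (-0.11 to 0.13). Averaged over the 3 matched doses, 0 clusters differed (limma, 599 at an unadjusted p under 0.05, smallest adjusted p 0.65), and the line model gave 0 for the difference of slopes (130, smallest adjusted p 1). For CPT1A the averaged difference was 0.27 with an interval from -0.12 to 0.67, and for PRDM1 1.36 from -0.51 to 3.24. Genes named for the difference of slopes, none past the threshold, reached from 2.95 (PRDM1), 2.53 (GPR183), 1.99 (CXCL8), 1.97 (FPR2), 1.91 (FOS) and 1.53 (FCAR) at 100 µM to -1.12 (HNRNPA1P27), -1.05 (BMS1P12), -1.04 (CXCL11) and -0.87 (SH3TC2). In 95.2% of tested clusters the averaged interval lay within 1.5-fold in both directions.

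Compared with the unstimulated array, the sterol and fatty acid synthesis lists shared less of the general offset than random lists, with members on both sides. INSIG1 was 9.95 on the unstimulated array and between 6.90 and 7.25 on the treated ones, the desaturase gene FADS2 was 9.11 against 7.45 to 7.56, SCD 10.59 against 9.30 to 9.68, and FASN 8.68 against 7.64 to 8.03. GPAM (1.36), MID1IP1 (1.08), ACACA (0.69) and PMVK (0.63) were higher in the mean of the treated arrays than on the unstimulated one. At 1 µM, 6 of 16 cholesterol genes were lower than on the unstimulated array with AA and 7 with OA, and 4 of 11 fatty acid synthesis genes with either acid. At 1 µM of either acid the median difference of the 16 cholesterol genes was 0.00, while random lists of similar brightness had medians of 0.74 (AA) and 0.77 (OA). For the 11 fatty acid synthesis genes it was 0.21 with AA and 0.27 with OA against 0.90 and 0.92. At 100 µM OA, other lists also lay low among random lists, with cell cycle genes at percentile 0.11 and LXR targets at 0.49. Ribosomal proteins lay at 0.83, glycolysis at 1.6 and the respiratory chain at 1.9, against 0 for cholesterol and 0.05 for fatty acid synthesis. ATF4 and p53 lists lay at 99.3 and 98.1, and the others between 6.44 and 71.3. A low percentile was not particular to lipid synthesis, although the cholesterol list had the lowest median, -0.06. At 1 µM AA, 6 of the 16 cholesterol genes held exactly the unstimulated value, as did 2.27% of all tested genes. Without such ties the cholesterol median was -0.20 with AA against 0.83 in random lists, and with rebuilt gene values -0.11 against 1.15. With OA, where 2 of the 16 were tied, these were 0.00 against 0.78 and 0.04 against 1.21. In the line model, relative to the other genes and their upward offset, the cholesterol list was shifted downward for AA (adjusted p = 1.1e-05) and OA (4.5e-14), and the fatty acid list for both (5.4e-04 and 3.8e-05). With an estimated correlation these had adjusted p = 0.25, 0.19, 0.25 and 0.25. Without the signal filter they had 0.24, 0.029, 0.34 and 0.28. The difference rests on 1 unstimulated array.

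Other lists passed in the line model too, likewise relative to the other genes. LXR targets were shifted downward for AA (adjusted p = 0.038; 0.43 with an estimated correlation) and OA (0.0028; 0.26), lymphoid markers for AA (0.014; 0.32) and OA (0.015; 0.32) and inflammatory genes for OA (0.014; 0.89). Toward AA in the difference of slopes were NRF2 (1.5e-06; 0.61), PPAR-responsive (0.020; 1.00), cell cycle (0.014; 1.00), macrophage (0.015; 1.00) and inflammatory genes (0.049; 1.00). For 4 of the 14 calls the list's own median slope had the other sign, LXR targets for AA (0.02) and, for OA, fatty acid synthesis (0.02), lymphoid (0.04) and inflammatory genes (0.07). Without the signal filter, 1 of the 9 downward calls of the line model held, cholesterol genes for OA, and 2 of the 5 upward ones, NRF2 and cell cycle genes for the difference of slopes.

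Single genes differed from the unstimulated array by far more than between doses. At 100 µM AA, 4093 clusters were at least 2-fold higher and 88 at least 2-fold lower than on the unstimulated array, and at 100 µM OA 3801 and 78. With the arrays centred on their medians the counts were 917 and 613 with AA and 753 and 428 with OA. At 1 µM the counts were already 3986 and 69 with AA and 4074 and 76 with OA. Against the mean of the 4 arrays at 1 and 10 µM, the 2-fold counts were 16 higher and 4 lower at 100 µM AA and 0 at 100 µM OA. The genes named for the AA line, none past the threshold, were SLC7A11 (4.41 log2 above unstimulated at 100 µM), RBM15, CLHC1, ZDBF2, C9orf72, CCPG1, NFIL3, FOS, PRDM1, ZNF791, VPS8 and P2RX7 (2.94). Lower were BMS1P12 (-4.88), DNM1P41, RNU2-1, CXCL11 (-2.07), TIMM8A, LINC01548, HNRNPA1P27, KRTAP21-2, NETO1-DT, OR7E87P, HNRNPU and LINC00965 (-1.38). For OA they were LYRM7 (2.81), GTF2H5, XPOT, APOL6, KHK, H2BC3, PPM1L, ZNF84, SAMD9L, ZNF460, EIF2AK2 and CDK1 (2.15), and, lower, ZNF468 (-4.30), DNM1P41, INSIG1 (-3.05), RNU2-1, MST1L, RPL6, TIMM8A, SERPINB10, FADS2 (-1.66), ZNG1E, RSRP1 and OR1F1 (-1.32).

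The slopes of AA and OA correlated at 0.955 across 9982 clusters, which are not independent replicates (covariance 0.0273). Simulated unchanged arrays that shared 1 unstimulated array gave 0.602 (covariance 0.0150) with the spread of the 7-array fit, which includes the unstimulated array's offset, and 0.592 (covariance 8.6e-04) with the spread of the treated arrays. Each simulation gave all arrays the same spread, while in the data the offset lay on the unstimulated array alone. Such an offset moves the slopes of AA and OA together. Neither simulated value is therefore what unchanged treated arrays would give here, and no shared response to the acids can be read from the comparison. Without the unstimulated array the observed value was -0.033 (covariance -1.9e-04).

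At the level of probe sets, the top-dose comparison called 293 upward and 129 downward at 100 µM AA of 178419 tested and 0 at 100 µM OA (limma, 18524 and 6140 at an unadjusted p under 0.05). The line model called 0 for AA and 0 for OA (20192 and 10830). Of 735 genes called at 100 µM AA with at least 4 tested probe sets, 700 (95.2%) had most probe sets moving the same way, among them LTBP1 with 33 of 36, FNDC3A with 29 of 31 and SLC7A11 with 19 of 19. The probe sets come from the same 7 hybridisations and are not an independent check.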

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

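The matched-dose comparison was planned, and the tests on noise of 1 array, on ties and on growth with dose were chosen before their results were seen; the other tests in this part were chosen only after the results were seen.

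The difference between the acids at 100 µM was singled out because it passed a test of the difference itself, with 487 clusters higher and 242 lower with AA (top-dose comparison, limma). The count was 0 without the 1 µM AA array and 0 without the 10 µM OA array (limma, 2091 and 2168 at an unadjusted p under 0.05), 3 without ties and 36 with rebuilt gene values. Among the genes called for this difference, the largest upward differences in log2 were LINC01226 (2.36), LTBP1 (1.99), LRRC37B (1.65), DHCR7 (1.47), C1QA (1.33), CABLES1 (1.28), MMP1 (1.22), FBN1 (1.07), CPEB2 (1.04), PLAUR (1.03), SYTL3 (1.03) and QPCTL (1.00). MMP1 was both above its lower-dose level with AA (7.22 against 6.46) and below it with OA (-0.45). The largest downward ones among the called genes were HNRNPA1P27 (-1.12), SIRPB1 (-0.93), ABCA2 (-0.89), UBE2D4 (-0.87), NFIX (-0.82), LCN12 (-0.82), CX3CR1 (-0.80), LCA10 (-0.72), SIRPD (-0.60), PTGS1 (-0.59), TEKTL1 (-0.57) and PHACTR3 (-0.56). ABCA2 (6.66 with AA, 7.55 with OA, 7.10 at the lower doses), UBE2D4, LCN12 and TEKTL1 lay below their lower-dose mean with AA and above it with OA. The values of HNRNPA1P27, ABCA2 and LCN12 were those of 1 probe set each, and over all their 14, 63 and 18 probe sets the median differences were -0.07, -0.12 and -0.24. LINC01226 and LCA10 had no probe sets assigned to their symbols alone and no rebuilt values. Of the 22 named genes with rebuilt values, LTBP1, DHCR7, CABLES1, MMP1, FBN1, PLAUR and SYTL3 were still called with them, and the other 15 had the same direction without a call. For averaged doses, 0 clusters were called (limma, 599 at an unadjusted p under 0.05) and the highest of the other splits of the 6 arrays gave 0; the 10 splits are too few for a share under 0.05.

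The first pattern is the 100 µM AA array, whose differences from the mean of the other 5 treated arrays had an SD of 0.180 log2 over tested clusters. On the other treated arrays, each set against its own other 5, the SD was 0.0902 to 0.109. No other treated array gave as many calls, but 6 arrays are too few for a share under 0.05 (1 of 6). Each other array was also tested with the 100 µM AA array among the 5 that gave the spread, which lowers its number of calls. The contrast in calls is thus partly set by the design. A wider or narrower signal range on the 100 µM AA array is argued against. The difference between its brightest and dimmest clusters, 0.0593, lay among those of the other treated arrays. With ties left out, the 100 µM AA array still had calls and no other array did. Its calls argue against ties as the whole cause, but the lack of calls on the others is partly set by the same design. Noise of 1 array was checked on the arrays at 10 µM, with 127 genes at least 1.5-fold apart on the 100 µM AA array, picked without those arrays. Of these, 81.1% differed the same way between 10 µM AA and 10 µM OA, with that difference centred on its median so that all genes give 50%. Uncentred, 79.5% did, 85.6% of 90 upward picks against 68.8% of all genes and 64.9% of 37 downward picks against 18.5%. The pick was made against a mean that included the 100 µM OA array. A shift shared by the 10 and 100 µM OA arrays would therefore also raise these shares. They argue against noise of the 100 µM AA array only where no such OA shift exists, which was not tested. At 1 µM the shares were 43.9% of 66 upward and 43.3% of 30 downward picks, where all genes, with equal values on both arrays counted as neither, give 35.1% and 46.9%; of 28 picked on the 100 µM OA array 78.6% differed the same way between 10 µM OA and 10 µM AA, though that pick was made against a mean that included the 100 µM AA array. A response that grows with the AA dose is a hypothesis that would give shares like the 81.1%, but so would a shift shared by the 10 and 100 µM OA arrays. A difference between cultures that happened to follow dose also stays open and untested.

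The second pattern is the unstimulated array. A narrower signal range on it is consistent with its brightest-minus-dimmest difference of -0.289, against 0.0198 to 0.0770 on the treated arrays. Uneven probe response on it is consistent with a within-gene spread of probe set differences 3.38 times the highest of the treated arrays. A response to either acid that is complete at 1 µM would also put most genes on one side, as 84.7% of tested clusters were, against 29.3% of all clusters, and cannot be told apart from a difference of that culture or hybridisation with 1 unstimulated array.

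The third pattern is that the sterol and fatty acid synthesis lists shared less of the unstimulated array's offset, with some members, such as INSIG1 and SCD, higher on that array and others, such as GPAM and ACACA, lower. The narrower range as its whole cause is argued against, because the cholesterol list at 1 µM OA lay -0.77 log2 from the median of random lists of similar brightness on the same arrays, at percentile 0 of them, also with ties to the unstimulated array left out and with rebuilt gene values. Random lists were drawn gene by gene, so the percentile took no account of members that vary together. At 100 µM OA, lists outside lipid synthesis also lay at extreme percentiles, such as cell cycle genes at 0.11 and ATF4 genes at 99.3. Such percentiles alone therefore neither single out lipid synthesis nor exclude another fault of the unstimulated array. With an estimated correlation, the cholesterol list's shift in the line model did not pass for either acid. Of the 609 probe sets of 25 genes of these lists, 35.0% were higher on the unstimulated array than on all 6 treated ones and 37.1% lower, against 20.3% and 55.3% of all named probe sets. By gene, 12 had more probe sets above and 12 more below. A response to either fatty acid already complete at 1 µM is a candidate explanation, with -0.74 at 1 µM AA, but another state of the unstimulated culture, such as its medium or lipid supply, cannot be told apart from it with 1 array.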

How the results depend on the processing

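The top-dose comparison and its alternatives, the array weights, the clusters without ties and the counts against the 4-array mean were chosen after the data had been seen; the others were planned. No replicates could be paired, because each condition had 1 array, but the matched-dose comparison paired the acids by dose. The line model's 0 calls became 1 (AA, and AA minus OA) with dose in linear µM and 1 (AA) with only the top dose contrasted. With array weights it called 2443 (AA), 2920 (OA) and 3082 (difference), from weights between 0.0056 for the unstimulated and 41.6 for the 10 µM OA array whose estimation did not converge. The matched-dose count of 0 became 16 with rebuilt gene values. Of 100 µM AA against lower doses, 837 clusters (584 higher, 253 lower) became 1721 without the signal filter (876 and 845, more clusters tested), 331 with the stricter filter, 98 with rebuilt values, 50 without ties (25 and 25, fewer clusters), 54 with a 1.5-fold minimum and 0 to 1650 leaving out 1 array. Without the 1 µM AA or the 10 µM OA array it was 0, without the 10 µM AA array 1650 and without the 1 µM OA array 547. The 0 of 100 µM OA became 332 without the filter and 0 to 361 leaving out 1 array, 361 without the 10 µM AA array. The 729 between the acids (487 and 242) became 1884 (905 and 979), 68 (62 and 6) with the stricter filter, 294 centred, 385 quantile normalized, 36 (34 and 2) rebuilt, 3 without ties, 62 at 1.5-fold, and 0 to 1781 leaving out 1 array. The 4181 clusters 2-fold apart between 100 µM AA and unstimulated cells (4093 and 88) became 2782 (stricter filter), 1530 (centred, 917 and 613), 1511 (quantile, 870 and 641), 6441 (1.5-fold), 49 (against 5 arrays) and 20 (against 4); the 3879 with OA (3801 and 78) became 1181 (753 and 428), 1206 (697 and 509), 6362, 4 and 0. The 0 AA probe sets became 422 in the top-dose comparison. The 14 list calls of the line model (5 up, 9 down) became 12 without the filter (9 up, 3 down), 3 of them among the 14. These 14 and the 8 at the top dose became 0 with estimated correlation; the 8 became 5 without the filter and 5 without ties. The slope correlation fell from 0.955 to -0.033 without the unstimulated array. With rebuilt values PTGES3 (0.30), PFKFB4 (-0.13) and NDUFC1 (-0.21) reversed; over 960 values of named genes, 608 kept direction and side of the threshold and 349 only direction. Except where the number of clusters or arrays changed, the cause was not tested. Without scanner files, signal over background was not known, so no limit for dim genes is given.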

Other observations

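The lists held 130 genes on the array below the signal filter, and their values, from the fit without the filter, were looked at after the data had been seen. PLIN2, the gene of the lipid droplet coat protein perilipin-2 and a PPAR-responsive gene, was 6.94 at 100 µM AA against 5.80 ± 0.06 (SD, 4 arrays at 1 and 10 µM), a rise of 1.14 log2 (adjusted p = 0.0056, limma), and 5.65 at 100 µM OA (-0.15, adjusted p = 0.63). PIR, an NRF2-responsive gene, was 4.27, 4.54 and 5.36 at 1, 10 and 100 µM AA and 4.34 at 100 µM OA (adjusted p = 0.029 for AA). Its level at the lower doses lay below the median of all clusters, and its signal over background was not known. PLIN2 held the same value, 5.77, at 1 µM AA and at 1 and 10 µM OA, so its spread was understated. The other PPAR-responsive genes below the filter did not rise at 100 µM AA. They were ANGPTL4 (0.01), PLIN4 (-0.01), CREB3L3 (-0.06), FABP4 (-0.14) and PDK4, which had no difference. Of the 131 memberships, 7 were called upward and 5 downward at 100 µM AA and 6 were called at 100 µM OA. Of the 12 calls with AA 10 had tied values among the 4 lower arrays, 4 of them with all 4 equal, and so had all 6 with OA, 4 of them with all 4 equal, so their spread was understated. The others called upward with AA were HERC5 (0.37) of the interferon list, SMPDL3A, ZMAT3, IL7R and SKIL, and those called downward were IFI27 (-0.12), also of the interferon list, DNMT3L (-0.05), ALAS2, HBB and MSR1. With OA, PLIN4 (0.26), a PPAR-responsive gene, TET1 (0.11), GPX2, SLC4A1 and ABCG1 were called upward and IL7R (-0.29) downward.

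DHCR7, the 1 cholesterol list member that rose at 100 µM AA, was 8.48 on the unstimulated array, 7.59, 7.71 and 8.77 at 1, 10 and 100 µM AA and 7.54, 7.36 and 7.31 at 1, 10 and 100 µM OA, while INSIG1 and SQLE stayed at 7.25 and 7.36 at 100 µM AA against 7.17 and 7.39 at 1 µM AA. In 15 of the 16 probe sets of DHCR7 the 100 µM AA difference went upward. The different courses of CXCL8 with AA (7.75, 8.19 and 8.88) and OA (7.34, 6.88 and 6.89) and of FOS with AA (7.65, 8.45 and 9.05) and OA (7.53, 7.06 and 7.14) rest on 1 array per dose.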
